A study of Mus musculus with 10 samples.

How the data were processed

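Gene expression was measured in mouse CD4+ T cells on Affymetrix arrays of whole-transcript probe sets, with 1 array per sample and 5 arrays in each of 2 groups. Per the labels' protocols, the cells came from spleens and lymph nodes of B10.BR mice and were sorted 2 times straight into Trizol LS. The anergic group carried the surface markers CD73 and FR4, and the control group was CD4+ without them. Total RNA was extracted, cleaned on columns and, after a check of its integrity, amplified and biotin-labelled with the Ovation Pico WTA V2 and Encore Biotin kits, which are made for very small amounts of RNA. The labels name no gate that removes regulatory T cells.

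The authors deposited 1 table of log2 expression values with 41345 probe sets and 10 arrays, rounded to 2 decimals. Base 2 was inferred, since the highest value, 13.81, lies above what a 16-bit scanner value gives as a natural log (11.1) or as log10 (4.82). The values were already on a common scale, with array medians from 3.25 to 3.34, but the background correction and normalization are not given in the sources used here. No detection calls or background levels were used here, so values near the bottom of the scale have no known relation to background. Folds against such values may be understated by an unknown amount. For arrays, the number of replicates limits the precision. There were 0 columns of per-sample values left unused.

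Probe sets were named from GEO's platform annotation. It gave 1 gene symbol for 23521 probe sets, several for 1814 and none listed for 16010. Probe sets with several symbols or none were left out of the gene tests. Entrez identifiers matched 23328 of the single-symbol probe sets to a RefSeq gene table of assembly GRCm38.p6, and the match changed 0 symbols. The build of the array's design is not given in the sources used here, so no coordinates are printed. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all 10 arrays stood for the gene, which left 22180 genes.

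The anergic arrays were compared with the control arrays gene by gene with limma 3.58.1 (lmFit and eBayes with default settings, two-sided) in R 4.3.3, with no covariate and no filter on dim genes. Benjamini-Hochberg adjustment was taken over all 22180 genes, and a gene was called at an adjusted p under 0.05. A log2 difference of 1 or more in either direction was the limit for a 2-fold change. Every log2 difference is the anergic mean minus the control mean, with limma's standard error (SE), and every fold is taken on the deposited scale. For the 3 sort markers, an exact two-sided permutation test over the 252 assignments of the arrays was added.

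Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists that had at least 5 measured members. Camera with an estimated correlation and fry were run beside it. The lists covered sort markers, anergy factors, inhibitory receptors and exhaustion, regulatory T cells, T follicular helper cells, naive and quiescent T cells, effector and memory T cells, the Th1 and cytotoxic, Th2 and Th17 programmes, the early TCR response, TCR signalling components, E3 ubiquitin ligases and adaptors, and T cell cytokines. Further lists held adenosine handling, folate handling, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, interferon response, the BCL2 family and death receptors, heat shock and handling stress, and chemokine receptors and homing. The remaining lists held markers of other cell types: B cell, plasma cell, CD8 T cell, NK cell, invariant or gamma-delta T cell, myeloid or dendritic cell, erythroid, platelet and stroma. Of 460 distinct genes on the lists, 398 were measured under a single symbol and the rest are not analysed here.

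The groups, tests, lists, other settings and the rule for naming genes were fixed before the data were examined. The rule took the 3 sort markers; the 10 genes with the largest positive and the 10 with the largest negative log2 difference among called genes whose 5 anergic values do not overlap the 5 control values, passing over predicted, variable-segment and pseudogene symbols; a fixed panel whatever its p (Egr2, Egr3, Cblb, Rnf128, Itch, Dgka, Nr4a1, Ndrg1, Pdcd1, Lag3, Ctla4, Tigit, Foxp3, Il2ra, Ikzf2 and Il2); and up to 4 members of each list with the smallest p. Where a further member of a list is given as an example, it was picked after its value was seen.

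Other settings tried were the replicate number as a block, leaving out each array in turn, leaving out the dimmest genes, quantile normalization or median-centring on top of the deposited values, array weights, a trended and robust variance, the mean of a gene's probe sets, and all probe sets in place of genes. After the data were seen, 3 more were added: the mean of the B cell list per array as a covariate, both control arrays with the highest B cell mean left out, and members of the regulatory T cell list left out of the other lists.

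The gene and list tests were tested on simulated data with the real means and spreads, in which 200 of 22180 genes were shifted. At a log2 shift of 0.5, 28% of the shifted genes were recovered, at 1 it was 80%, and at 2 and at 3 it was 100%. There were 14 false calls, 8.33% of all calls. A shifted list was called, and 0 other lists were. The genes were drawn independently of each other, so this does not test lists whose members vary together.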

Results

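The series profiled 2 populations of mouse CD4+ T cells, each on 5 arrays. Anergy is a state in which a T cell that has met antigen no longer responds to it, and in the mouse anergic CD4+ T cells carry high surface CD73, an ectoenzyme that makes adenosine, and FR4, a folate receptor family member. Anergic CD4+ cells positive for both markers were compared with CD4+ cells negative for both. Array medians lay between 3.25 and 3.34 on the deposited log2 scale. Across all 22180 genes the median log2 difference, anergic minus control, was -0.01. Correlations between arrays were 0.966 to 0.980 within the anergic group, 0.956 to 0.976 within the control group and 0.947 to 0.976 between the groups. The first principal component held 46.1% of the variance of the 6392 genes with a mean log2 value above 5, and its scores were negative for all 5 anergic arrays and positive for all 5 control arrays. The labels do not say that the arrays came from separate animals, so the p-values measure only the spread between these samples, which may be technical.

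Both genes that defined the gates followed the labels. Nt5e, which encodes CD73 (Entrez 23959), stood at 8.33 ± 0.23 in the anergic arrays against 4.08 ± 0.20 in the control arrays (SD, n = 5 each), 18.9-fold higher. Izumo1r, which encodes FR4 (Entrez 64931), stood at 10.61 ± 0.13 against 7.22 ± 0.15, 10.5-fold higher. In an exact two-sided permutation test over all assignments of the arrays each gave p = 0.00794, the smallest that this design allows. These genes check the sort and are not a finding. Cd4 (Entrez 12504), which both gates required, was 9.13 ± 0.15 in the anergic and 9.47 ± 0.28 in the control arrays, a log2 difference of -0.35 with an SE of 0.14 that did not pass over all genes (limma, Benjamini-Hochberg adjusted p = 0.257), while its exact permutation p was 0.0397. Among these 3 genes, adjusted over the list alone, 2 were higher and Cd4 was lower.

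Beyond the sort markers, Maf, a transcription factor of helper and regulatory T cells, was 46.3-fold higher in the anergic arrays (9.26 ± 0.34 against 3.72 ± 0.12), and Il2ra, the alpha chain of the IL-2 receptor, was 43.1-fold higher (9.28 ± 0.04 against 3.85 ± 0.47). Foxp3, the lineage factor of regulatory T cells, was 32.4-fold higher (9.29 ± 0.43 against 4.27 ± 0.43), and Ikzf2, which encodes the transcription factor Helios, 31.6-fold (9.08 ± 0.18 against 4.09 ± 0.18). Dntt, the template-independent DNA polymerase of developing lymphocytes, was 11.9-fold lower (3.09 ± 0.22 against 6.66 ± 0.45). For each of these genes all 5 anergic values lay on one side of all 5 control values, which the rule for naming the largest changes required. In all, 696 genes were higher and 243 lower in the anergic arrays (limma, Benjamini-Hochberg), and 337 of these 939 differed at least 2-fold, 261 of them higher and 76 lower. The 5 anergic values lay wholly above or wholly below the 5 control values for 789 of the called genes; over all genes this held for 4.63%, where chance gives 0.794%. In the test without anergic array 4, 157 genes were called lower. With the B cell list mean per array as a covariate, 326 genes were higher and 127 lower.

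**Figure D1:**
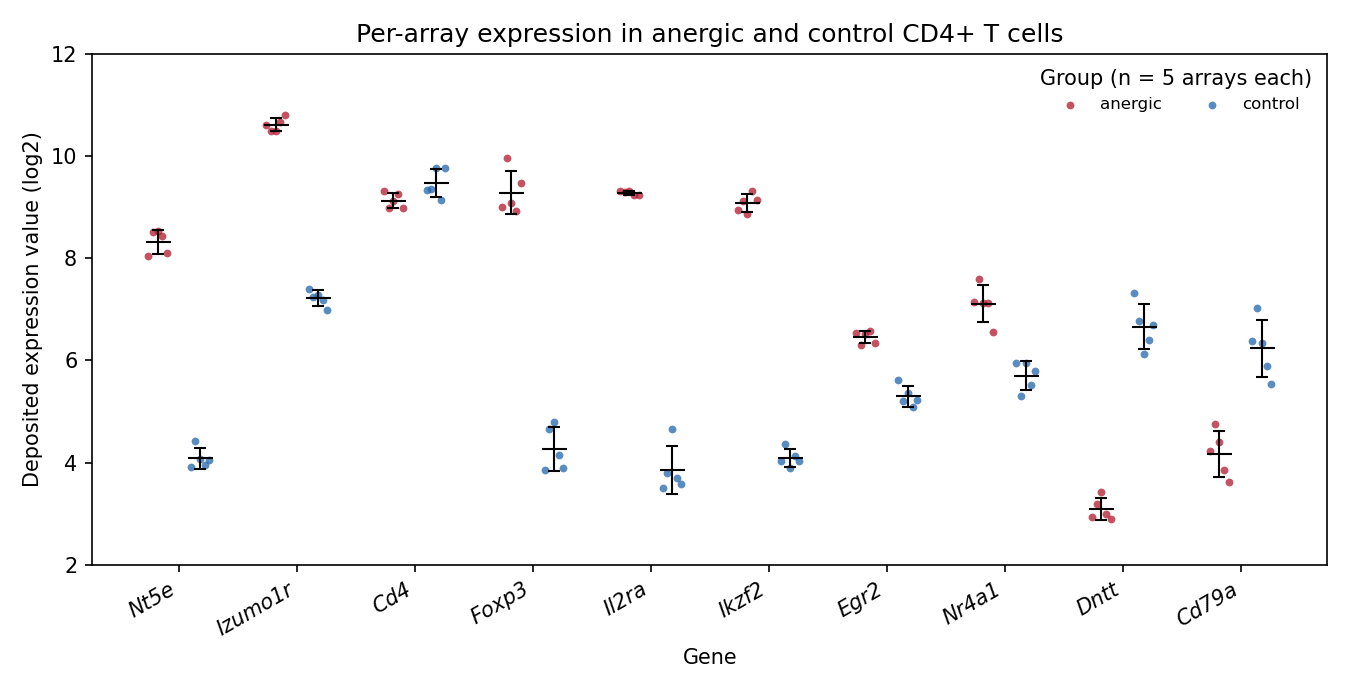
Deposited expression values (log2, vertical axis) of 10 genes in each of the 5 anergic (red) and 5 control (blue) arrays; black bars give the mean ± SD of each group. Foxp3, Il2ra and Ikzf2 sit near 9 in the anergic and near 4 in the control arrays. Dntt and Cd79a lie lower in every anergic array than in any control array, as the rule that named them required. The groups overlap for Cd4.

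Among the lists tested, the regulatory T cell list had the median furthest from 0. Of its 23 measured members, 20 rose and 3 did not pass (22 rose adjusted over the list alone). The median log2 difference was 2.03 (camera adjusted p = 2.57e-70, and 6.83e-06 with an estimated correlation). Besides Foxp3 (adjusted p = 2.01e-09), Il2ra (6.08e-11) and Ikzf2 (6.04e-12), Lrrc32, which presents latent TGF-beta at the cell surface, rose 27.9-fold (SE 0.16 on the log2 scale, 6.83e-11), and Nrp1, a receptor found on thymus-derived regulatory T cells, 17.1-fold (SE 0.14, 6.08e-11). Gpr83, Tnfrsf4 and Ikzf4 rose by 3.86, 3.38 and 2.96. The log2 differences of Il10, Socs2 and Plagl1, 0.30, 0.41 and 0.25, did not pass. When any 1 array was left out, the number of members called higher was 20 as well. The mean of the list per array was 6.49 to 6.67 in the anergic and 3.91 to 4.08 in the control arrays. Outside this list, Il2rb, the shared beta chain of the IL-2 and IL-15 receptors, rose by 5.00 (SE 0.13, adjusted p = 8.02e-12). Stfa3 rose by 4.50 (SE 0.20, adjusted p = 1.73e-09), but its near-identical stefin paralogs make the assignment to this gene uncertain.

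Anergy factors rose in part. Of 20 measured members, 9 rose, 1 fell and 10 did not pass (11 rose and 2 fell adjusted over the list alone). The median log2 difference was 0.42 (camera adjusted p = 5.03e-11, and 0.0114 with an estimated correlation). Egr2, a transcription factor induced by TCR signals without costimulation, rose from 5.30 ± 0.21 to 6.46 ± 0.12, a log2 difference of 1.16 (SE 0.12, adjusted p = 2.01e-05). Nr4a1, an immediate TCR target, rose by 1.41 (SE 0.18, 1.39e-04), and Nrn1, a surface protein of anergic and regulatory cells, by 2.89 (SE 0.17, 5.48e-08). The largest rise on this list, 4.09, was that of Nrp1, which is also on the regulatory T cell list. Cd5, Nfatc1 and Nr4a3 rose by 0.85, 0.72 and 0.93, and Ikzf1 fell by 0.51. Without any 1 of the anergic arrays, or without control array 3 or 5, no anergy factor was called lower. Smaller rises were measured for Egr3 (0.82, SE 0.20, adjusted p = 0.0268) and for Cblb, an E3 ligase that restrains TCR signalling (0.43, SE 0.11, 0.0354). The E3 ligases Itch and Rnf128 showed log2 differences of 0.17 (adjusted p = 0.638) and -0.01 (0.990), Ndrg1 showed 0.28 (0.739) and Dgka, a kinase that removes diacylglycerol, -0.51 (0.0695). Rnf128 was at the bottom of the scale in both groups, at 2.54 and 2.55. The call of Egr3 ended without anergic array 2, 3 or 4 or control array 1, 2 or 4 (adjusted p 0.0601 to 0.0754), and that of Cblb without any of the arrays except anergic 2 and control 5 (0.0580 to 0.0949), while Dgka was called lower without control array 1 (0.0256), with array weights (0.0465), with the trended and robust variance (0.0298), with the B cell covariate (-0.82, 0.0439) and without both control arrays of highest B cell mean (-0.72, 0.00713). Leaving out both control arrays with the highest B cell mean ended the calls of Egr3 (0.148) and Cblb (0.157) and lowered the number of anergy factors called higher to 5 (list median 0.36), and the B cell covariate lowered it to 4 (0.37).

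Inhibitory receptors and T follicular helper genes rose in part. Of 15 measured members of the inhibitory receptor list, 10 rose and 5 did not pass (10 rose and 1 fell adjusted over the list alone; median log2 difference 0.86, camera adjusted p = 1.58e-18). Ctla4 rose 16.7-fold, Tigit 18.3-fold, Pdcd1 (PD-1) 6.18-fold, Cd200 4.24-fold, Lag3 3.38-fold and Entpd1 (CD39) 3.09-fold, with adjusted p from 8.63e-11 for Ctla4 to 6.93e-06 for Lag3 and no overlap between the groups. Havcr2 and Btla showed differences of -0.13 and 0.10 that did not pass. Of the 16 follicular helper genes, 9 rose and 7 did not pass (11 rose adjusted over the list alone; median 0.84, camera adjusted p = 5.02e-21). Apart from Maf (adjusted p = 8.02e-12), these included Cxcr5, the receptor that guides cells to B cell follicles, at 3.83 (SE 0.20, 1.07e-08), and Bcl6, the lineage factor, at 1.27. Members shared with the regulatory T cell list numbered 2 and 1. With such members left out, 8 of 13 inhibitory receptors and 8 of 15 follicular helper genes were higher. This removal cannot tell which cells expressed the remaining genes, since arrays average all cells of a gate.

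Effector and homing genes rose in part, and naive T cell genes fell in part. Of 21 effector and memory genes, 15 rose and 6 did not pass (15 rose adjusted over the list alone). The effector list median was 0.85 (camera adjusted p = 2.71e-30, and 0.00147 with an estimated correlation). S100a6 rose by 3.95, S100a4 by 2.95 and Ahnak by 2.25, while Cd69 showed 0.05. Cd44, the standard marker of antigen-experienced T cells, rose by 0.99. Among 20 chemokine receptors and homing molecules, 11 rose and 9 did not pass (12 rose adjusted over the list alone). Their median was 0.72 (camera adjusted p = 2.26e-18, and 5.41e-04 with an estimated correlation). Those that rose included Itgae (CD103), also on the regulatory T cell list, at 3.44 and Cxcr3 at 2.84. Itgb8, part of an integrin that activates TGF-beta, rose by 2.12. The 15 naive and quiescent T cell genes had 6 that fell and 9 that did not pass (1 rose and 9 fell adjusted over the list alone). The naive list median was -0.40 (camera adjusted p = 8.61e-08, and 0.0468 with an estimated correlation). Those that fell included Satb1 (-1.09, SE 0.15, adjusted p = 2.91e-04), Dapl1 (-1.01), Actn1 (-0.95) and Lef1 (-0.61). The B cell covariate gave 3 naive genes called lower, with a list median of -0.50.

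Genes of all 3 helper programmes rose in part. On the Th1 and cytotoxic list, 4 of 15 members rose, 1 fell and 10 did not pass (7 and 1 adjusted over the list alone). The list median was 0.38 (camera adjusted p = 5.99e-07), and 0.25 without anergic array 2. Nkg7, a granule membrane protein, and the chemokine Ccl5 rose by 2.82 and 2.07, Ifng and Il18rap by 0.73 each, and Prf1, which encodes perforin, fell by 1.59 (SE 0.23, adjusted p = 6.22e-04). Tbx21 and Gzmb showed 0.24 and 0.05. With the B cell covariate 2 members were called higher and none lower, with a list median of 0.33. On the Th2 list, 3 of 8 rose and 5 did not pass (4 adjusted over the list alone; median 0.38, camera adjusted p = 5.80e-05). They were the chemokine receptors Ccr8 (2.42) and Ccr4 (2.40) and, at 0.54, the transcription factor Gata3 (adjusted p = 0.0414), whose call held only without anergic array 2, control array 1 or control array 3 among the settings that left out 1 array (0.0617 to 0.110 in the others) and ended with the trended and robust variance (0.0586); the cytokines Il4, Il5 and Il13 showed 0.43, -0.03 and -0.17. On the Th17 list, Ccr6 (2.59) and the ligand-activated factor Ahr (1.08) rose and 7 of 9 did not pass (3 rose adjusted over the list alone; median 0.14, camera adjusted p = 0.00105), while Il17a showed 0.08. Of 18 cytokines, 5 rose and 13 did not pass (10 adjusted over the list alone; median 0.31, camera adjusted p = 2.16e-08): Xcl1 by 1.95, Tnfsf11 by 1.87, Il21 by 1.20, Csf1 by 1.08 and Ifng. Il2 stood at 3.14 ± 0.27 against 2.83 ± 0.07, near the bottom of the scale (log2 difference 0.31, SE 0.13, adjusted p = 0.278).

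Genes of the early TCR response rose in part, without a shift of the signalling components in a common direction. Of 19 early response genes, 8 rose and 11 did not pass (11 rose adjusted over the list alone). The list median was 0.52 (camera adjusted p = 3.54e-10, and 0.0238 with an estimated correlation). Tnfrsf9 (4-1BB), also on the regulatory T cell list, rose by 2.82 (SE 0.13, limma adjusted p = 3.21e-09). Irf4 rose by 1.51 (SE 0.20, limma adjusted p = 2.23e-04), and Nr4a1, Egr2 and Egr3 rose as well. Fos, Fosb and Ier2 showed -0.01, -0.20 and -0.04. In the test with the B cell covariate 4 members were called higher, with a list median of 0.54. Of 18 TCR signalling components, 1 rose, 2 fell and 15 did not pass (2 and 2 adjusted over the list alone). Their median was -0.01 (camera adjusted p = 0.934). It turned to 0.01 after quantile normalization and 0.03 after median-centring, and lay between -0.06 and 0.06 when single arrays were left out. Of the 18 components, 6 had an unadjusted limma p under 0.05. A fry test for changes in either direction gave an unadjusted p of 6.69e-08. Themis (-0.77, adjusted p = 0.00149) and Grap2, an adaptor of SLP-76 (-0.72, 0.0102), fell, and Ptpn22, a phosphatase that restrains TCR signals, rose by 0.46 (0.0163), a call that ended without both control arrays of highest B cell mean (0.100). Of 13 E3 ligases and adaptors, Cblb and Ndfip1 rose (3 rose adjusted over the list alone), with a median of 0.17. When single arrays were left out, the median lay between 0.10 and 0.22, and 0 or 1 members were called higher. Ndfip1, at 0.54 (adjusted p = 0.0313), lost its call without anergic array 1, 2, 3 or 5 or control array 2, 3 or 5 (0.0540 to 0.0875). The list's camera adjusted p was 0.0424, and 0.240 with an estimated correlation; its call also ended without anergic array 1, 2 or 3 or control array 1, 2 or 4 (0.0512 to 0.151), after quantile normalization (0.0926), with array weights (0.0537), with the trended variance (0.0522), without the dimmest genes (0.103), without both control arrays of highest B cell mean (0.223) and with the B cell covariate (0.834).

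Genes of adenosine and folate handling were tested without the sort markers Nt5e and Izumo1r. Of 8 adenosine genes, 4 rose and 4 did not pass (4 adjusted over the list alone; median 0.46, camera adjusted p = 1.03e-05). Entpd1, which works upstream of CD73 and is also on the regulatory T cell list, rose by 1.63 (SE 0.11, limma adjusted p = 1.98e-07). Adk, which phosphorylates adenosine, rose by 0.94 (5.68e-05) and Dpp4 by 0.91 (1.32e-04). The transporter Slc29a1 rose by 0.77 (0.0430), with overlap between the groups, and its call held only without control array 1 or control array 4 when single arrays were left out (0.0556 to 0.114 in the others) and ended with the mean of its probe sets (0.127) and without both control arrays of highest B cell mean (0.105). Of 13 folate genes, 0 rose and 0 fell (limma; 2 had an unadjusted p under 0.05; 1 rose adjusted over the list alone; median 0.11, camera adjusted p = 0.118), and the smallest p belonged to Tyms (0.43, adjusted p = 0.0634), which was called higher without control array 5 (0.0214), after median-centring (0.0396) and with array weights (0.0476).

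Cell cycle genes shifted slightly upwards. Of 24, 3 rose and 21 did not pass (5 adjusted over the list alone; median 0.21, camera adjusted p = 5.32e-05). They were Rrm2 (1.17, adjusted p = 0.00847), Mcm6 (0.70, 0.00298) and Top2a (0.62, 0.00507), while Mki67 showed 0.46 and Stmn1 -0.42. With the B cell covariate 1 was called higher, with a list median of 0.25, Rrm2 at 1.45 (adjusted p = 0.0544) and Top2a at 0.72 (0.0607). Of 12 glycolysis genes, 3 rose and 9 did not pass (3 adjusted over the list alone; median 0.24, camera adjusted p = 1.09e-04, and 0.159 with an estimated correlation). Tpi1 and the glucose transporter Slc2a3 rose by 1.07 and 1.02, and Gapdh by 0.41 (adjusted p = 0.0343), but the call of Gapdh held only without anergic array 1, control array 1 or control array 2 among single arrays (0.0657 to 0.0879 in the others) and ended with the mean of its probe sets (0.18, 0.564). For glycolysis the B cell covariate gave 1 gene called higher, with a list median of 0.27 and Gapdh at 0.54 (adjusted p = 0.0990). Of 12 cholesterol synthesis genes, 0 passed over all genes or adjusted over the list alone (limma; 3 had an unadjusted p under 0.05), with a median of 0.19, a camera adjusted p of 0.0159 and one of 0.273 with an estimated correlation; the camera call ended without anergic array 1 (0.0547), control array 2 (0.0581) or the dimmest genes (0.0586), and with the B cell covariate (0.145). The same held for 12 genes of the BCL2 family and death receptors, with 0 passing over all genes or adjusted over the list alone (limma; 2 at an unadjusted p under 0.05), a median of 0.14, a camera adjusted p of 0.0230 and one of 0.103 with an estimated correlation; that call ended without anergic array 1 (0.0669) or the dimmest genes (0.0779), and with the B cell covariate (0.168). Of 22 oxidative phosphorylation and 19 interferon response genes, 0 passed over all genes or adjusted over the list alone (limma; 1 and 3 at an unadjusted p under 0.05; medians 0.04 and 0.09; camera adjusted p 0.818 and 0.725). On the interferon list, Ifit2 (-0.46, adjusted p = 0.239) was called lower without control array 2 (-0.63, 0.0154), without both control arrays of highest B cell mean (-0.66, 0.0283) and with the B cell covariate (-0.93, 0.0422), which moved the list median to -0.02. The oxidative phosphorylation median was below 0 without control array 4 (-0.01) or 5 (-0.02). Without both control arrays of highest B cell mean the oxidative phosphorylation list was called higher (median 0.14, camera adjusted p = 0.0243). Of 11 heat shock genes, the co-chaperone Bag3 rose (0.82, adjusted p = 0.00112; 1 over the list alone; median 0.05, camera adjusted p = 0.151), while Hspa1a showed -0.41.

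**Figure D2:**
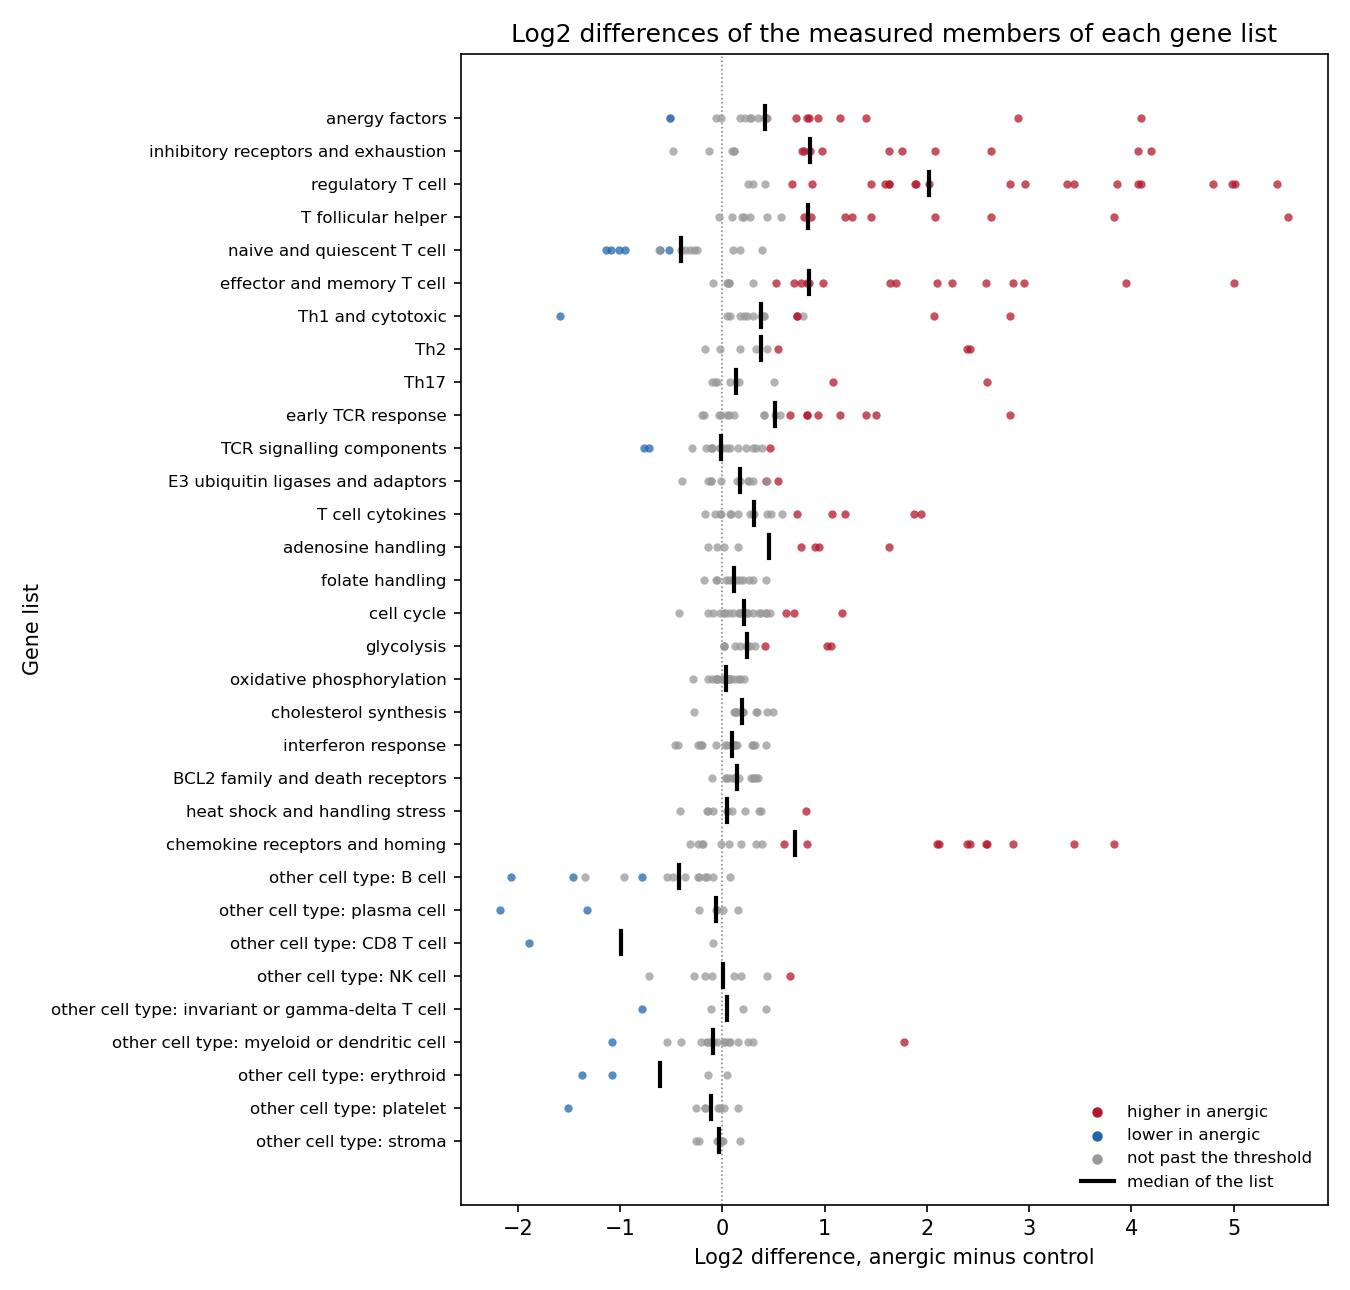
Log2 difference, anergic minus control (horizontal axis), of each measured member of 32 gene lists (vertical axis); red and blue points passed the test over all genes as higher or lower, grey points did not, and black bars mark list medians. The regulatory T cell list has the highest median, 2.03, and 20 of its 23 members are red. The naive T cell and B cell lists have medians of -0.40 and -0.43. The CD8 T cell and erythroid lists, with only 2 and 4 measured members, have the lowest medians, -0.99 and -0.61.

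Among the 10 genes named for the size of their fall, Dntt showed a log2 difference of -3.57 (SE 0.19, adjusted p = 1.21e-08), Cd24a, a surface protein that is high on immature lymphocytes and B cells, -2.46 (SE 0.40, 0.00149), and Cd8b1, the beta chain of CD8, -1.89 (SE 0.18, 7.76e-06). The others were Pdlim4 (-2.33), Nacc2 (-2.30), the class II gene H2-Ea (-2.13), Amigo2 (-2.09), the monocarboxylate transporter Slc16a5 (-2.09), Cd79a, a signalling chain of the B cell receptor (-2.07), and Tmie (-1.92), with adjusted p from 4.01e-06 for Amigo2 to 9.59e-04 for H2-Ea. With the B cell covariate the calls of Cd24a (-1.48, adjusted p = 0.218) and H2-Ea (-1.26, 0.169) ended.

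B cell markers fell in part. Of 14 measured, 3 fell and 11 did not pass (8 fell adjusted over the list alone; median -0.43, camera adjusted p = 3.16e-07, and 0.0814 with an estimated correlation). Besides Cd79a (6.24 ± 0.56 in the control and 4.17 ± 0.45 in the anergic arrays) these were Ly6d, at -1.46 (limma adjusted p = 0.0139), and Blk, at -0.79 (0.0206). The call of Blk ended without anergic array 1 or 4 or control array 2 or 5 (0.0529 to 0.0566). With the B cell covariate Ly6d was at -0.21 (0.709). Ly6d is on the list behind that covariate, so it was adjusted in part for itself. Ms4a1 (CD20) differed by -1.34 (adjusted p = 0.0713) and was called lower without control array 2 or 5 (lowest adjusted p 0.0139), without the dimmest genes (0.0452) and with array weights (0.0348). The mean of the B cell list per array was 3.38 to 3.67 in the anergic arrays and 4.17, 4.79, 4.06, 3.84 and 3.65 in control arrays 1 to 5. Of 7 plasma cell genes, Iglv1 (-2.17, adjusted p = 7.05e-04), a light chain segment with close relatives, and Jchain (-1.32, 0.00599; -0.61, 0.456 with the B cell covariate) fell and 5 did not pass (2 adjusted over the list alone). The plasma cell median was -0.06, and between -0.17 and -0.05 when single arrays were left out. Its camera adjusted p was 0.0237, and 0.0727 with an estimated correlation. The camera call ended without anergic array 5 (0.0663) and with the B cell covariate (0.181).

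Markers of other cell types gave at most 2 calls per list. The CD8 T cell, invariant or gamma-delta T cell and erythroid lists had under 5 measured members and were not tested with camera. Of the 2 CD8 T cell genes, Cd8b1 fell and Cd8a showed -0.09 at about 3 in both groups (1 over the list alone). Of 8 NK cell genes, Klrb1c rose by 0.66 (adjusted p = 0.0421; 1 rose and 1 fell adjusted over the list alone; median 0.00, camera adjusted p = 0.960), and its call held only without anergic array 1 or control array 1 among single arrays (0.0620 to 0.107 in the others) and ended with array weights (0.0520). Of 4 measured invariant or gamma-delta T cell genes, Blk alone fell (1 over the list alone; median 0.04, mean -0.07). Of 19 myeloid or dendritic cell genes, Cybb, a subunit of the phagocyte oxidase, rose by 1.77 (3.69e-04) and Ly86 fell by 1.08 (0.0335), and 17 did not pass (1 and 1 adjusted over the list alone; median -0.09, camera adjusted p = 0.713). Ly86 lost its call without anergic array 1, 3, 4 or 5 or control array 4 (0.0683 to 0.0858), and with the B cell covariate its log2 difference was -0.14 (0.884). Of 4 erythroid genes, the carbonic anhydrases Car1 (-1.37, 0.0186) and Car2 (-1.07, 0.0123) fell (2 over the list alone; median -0.61), Car1 not without anergic array 5 or control array 2 (0.0564 to 0.0566), and neither without both control arrays of highest B cell mean (0.0601 and 0.0702). Of 8 platelet genes, the integrin chain Itgb3, also found on other cells, fell by 1.51 (5.73e-05) and 7 did not pass (1 over the list alone; median -0.11, camera adjusted p = 0.0519, which passed without anergic array 3 or 5 or control array 3, at 0.0313 to 0.0440, and after median-centring, at 0.0474; fry adjusted p = 0.00140). Of 8 stroma genes, 0 passed over all genes or adjusted over the list alone (limma; 2 at an unadjusted p under 0.05; median -0.03, which turned to 0.01 after either scaling alternative; camera adjusted p = 0.387).

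Of the 29 lists tested, camera called 20, 17 higher and 3 lower, and fry called 19. The fry calls added the platelet list, as lower, and did not include the E3 ligase (adjusted p = 0.0538) and cholesterol synthesis (0.116) lists. With an estimated correlation 14 calls held: anergy factors, inhibitory receptors, regulatory T cell, follicular helper, naive, effector and memory, Th1, Th2, Th17, early TCR response, cytokines, adenosine handling, cell cycle, and chemokine receptors and homing. The weakest of these was the naive list, with an adjusted p of 0.0468 with an estimated correlation, and the firmest was the regulatory T cell list, at 6.83e-06. Of the 80 called genes among the 137 named, 26 lost their call with the B cell covariate, at adjusted p from 0.0544 to 0.884, and for 24 of these the SE grew. The log2 difference shrank by over 1.5 times for 7 of them (Cblb, Cd24a, H2-Ea, Jchain, Ly6d, Ly86 and Slc29a1). It was larger than without the covariate for 8 (Gapdh, Gata3, Grap2, Klrb1c, Lef1, Ndfip1, Rrm2 and Top2a), and 11 lay in between (Bag3, Blk, Car1, Car2, Dapl1, Egr3, Il18rap, Iglv1, Prf1, Ptpn22 and Slc2a3). Ly6d and Blk are on the list behind the covariate, so they were adjusted in part for themselves.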

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

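The tests of the regulatory T cell list and of the B cell list were chosen only after those results were seen, and the B cell covariate was added after the data were seen. The tests of Dntt, Cd8b1 and Cd24a and the counts over other splits were set down before their own results.

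Regulatory T cell genes had the highest median of the lists tested, 2.03, and regulatory T cells, which carry CD73 and FR4 themselves, are a candidate explanation as part of the anergic gate. Array scaling that shifts all values of an array is argued against by array medians between 3.25 and 3.34. The list median was 2.03 after quantile normalization, which adds little because the arrays were already on a common scale. A mislabelled array is argued against by a gap of 2.41 between the lowest anergic and the highest control array in the list mean. Foxp3-negative anergic cells as the whole source are argued against by Foxp3 itself, with a log2 difference of 5.02 (SE 0.22) and no overlap between the groups. For the other members they stay open, since the anergy factors outside the list had a median of 0.40 and arrays average all cells of a gate, so for these genes the sources cannot be told apart. Within the groups the listed genes varied together no more than most random lists (mean pairwise correlation 0.0248, above 28.0% of 10000 random lists of similar expression). This correlation cannot decide on regulatory T cells, because their share may be alike in all arrays. The Foxp3 values argue against an anergic gate without Foxp3-expressing cells, but the share of such cells stays open. A sort that also gates on Foxp3 would separate the sources.

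The B cell genes had a median log2 difference of -0.43, with 3 of 14 called lower (camera adjusted p = 3.16e-07, and 0.0814 with an estimated correlation). B cell RNA in some control arrays is a candidate explanation, since the 14 genes rose and fell together among the arrays of a group. Their mean pairwise correlation was 0.358, above 100% of 10000 random lists of similar expression. Scaling that shifts whole arrays is argued against by array medians between 3.25 and 3.34. The list median was -0.40 after quantile normalization, which could move little on arrays already on a common scale. The levels were low, with Cd79a at 6.24 and Ms4a1 at 4.29 in the control arrays against 9.47 for Cd4, the cells were sorted 2 times as CD4+, and control array 5, with a list mean of 3.65, lay below anergic array 2, at 3.67. Of these genes Blk is also on the invariant or gamma-delta list, and class II genes are shared with dendritic cells.

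Dntt, Cd24a and Cd8b1 had log2 differences of -3.57, -2.46 and -1.89. For Dntt and Cd8b1, B cell RNA as the whole cause is argued against, since they kept at least 94.5% of their log2 difference and their calls with the B cell mean as a covariate. Cd24a kept 60.1% but its call ended, as the log2 difference went from -2.46 (SE 0.40) to -1.48 (SE 0.51), so a share from B cells cannot be told apart from other sources. Young T cells that recently left the thymus, in the control gate, stay possible: of 8 further measured thymocyte genes Aqp11 alone was lower, and their median was -0.061.

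In its counts of genes the real grouping stood out from other splits of the 10 arrays, of which 100 of 126 were drawn. Of the 100 splits, the real one alone gave as many as 696 genes higher (highest other 1) and 243 lower (highest other 1). The same held for the 337 changed at least 2-fold (highest other 0). A share of 1 in 100 makes chance unlikely but does not exclude it. The other splits mixed the groups, so the real difference widened the spread within their sides and lowered their counts. For the 20 lists called with the preset correlation, 4 of the 100 splits were as large, the real one included, and the highest other was 21. Another split thus exceeded the real count, so this count does not exclude chance. The 3 other splits with as many kept 4 of the 5 anergic arrays on one side, and splits with 3 on one side reached at most 10 lists. Over all other splits, 86 called at least 1 list, with a median of 3. With an estimated correlation the real grouping called 14 lists and the other splits 0, where the mixing of the groups also counts against a call.

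In 12 of 274 combinations of a named gene and a group, 1 array stood far from the other 4, measured as its gap to the nearest value over the group's range. Chance gives about 5% of combinations, so there were no more flags than by chance. Among control arrays, array 2 was high for Nt5e (4.43 against 3.92 to 4.06; 0.725) and low for Ifit2 (5.62 against 6.37 to 6.64; 0.735) and Txndc5 (4.59 against 5.29 to 5.53; 0.745). Control array 3 was high for Il2ra (4.66 against 3.50 to 3.80; 0.741), control array 4 low for Slc16a5 (8.19 against 9.21 to 9.28; 0.936) and control array 5 low for H2-Ea (4.06 against 5.80 to 6.36; 0.757). Among anergic arrays, array 5 was low for Ndrg1 (4.67 against 5.05 to 5.20; 0.717) and Cxcr5 (7.74 against 8.23 to 8.40; 0.742), and array 3 high for Derl3 (3.88 against 2.92 to 3.19; 0.719). Anergic array 2 was high for Slc29a1 (5.85 against 5.16 to 5.35; 0.725), Ms4a1 (3.38 against 2.78 to 2.90; 0.800) and Col3a1 (3.81 against 3.18 to 3.36; 0.714).

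Probe sets without a single gene symbol, which the gene tests did not use, also differed between the groups. Of 17824, 150 were higher and 67 lower in the anergic arrays (limma, Benjamini-Hochberg over all probe sets), 102 and 32 of them at least 2-fold.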

How the results depend on the processing

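The settings built on the B cell list and the removal of regulatory T cell genes from other lists were chosen after the data were seen. No called log2 difference among the named genes changed sign in any setting, and 0 of the 939 called genes did in the settings that tested genes. Leaving out 1 array at a time gave 567 to 723 genes higher, 157 to 245 lower, 317 to 352 changed at least 2-fold and 17 to 21 lists called; the 157 came without anergic array 4, and the cause was not tested. Of 80 called named genes, 70 kept their call in each of these settings, and 54 in every setting tried; 26 lost it with the B cell covariate. With the B cell mean as a covariate, 326 genes were higher and 127 lower, and 386 of its 453 calls were among the 939; the covariate itself differs between the groups, so standard errors grow, as for Cd24a (from 0.40 to 0.51), and how much of the loss of calls this accounts for was not tested. That setting gave 326 genes changed at least 2-fold and 15 lists. Without control arrays 1 and 2, which had the highest B cell means, 581 genes were higher, 245 lower and 350 changed at least 2-fold, and 20 lists were called. Counts in the remaining settings stayed within 1.5 times; median-centring, which moved the median of all genes from -0.01 to 0.03, made 79.9% of calls higher, against 74.1%. Deviations of same-numbered arrays correlated at 0.0566, -0.0273, 0.201, 0.0894 and 0.146, and array 4 alone correlated best with its own number. These values show no clear pairing, but they cannot exclude that same-numbered arrays share animals or a sort. With the replicate block, 685 genes were higher, 259 lower and 342 changed at least 2-fold, and 19 lists were called. The camera call of the E3 ligase list ended (adjusted p = 0.0503). Among the named genes 4 lost their call, Slc29a1 (limma adjusted p = 0.0899), Gapdh (0.0818), Gata3 (0.0509) and Klrb1c (0.0979). A call was gained by 2, Ms4a1 as lower (0.0147) and Rora as higher (0.0446). Signal over background is unknown here, so folds of genes near the bottom of the scale are limited by background of unknown size.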

Other observations

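The genes in the next paragraph were picked after their values were seen, and the IL-2 test was set down before its result.

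Further called genes of large change were on none of the fixed lists. P2rx7, the receptor for extracellular ATP, rose by 3.60 (SE 0.11, limma adjusted p = 5.49e-11). The inflammatory caspases Casp4 and Casp1 rose by 2.89 (SE 0.22, 8.53e-07) and 2.23 (SE 0.16, 3.82e-07). Rgs1 and Rgs16, which shorten signals from G protein-coupled receptors, rose by 3.52 and 2.71, and Ptger2, a receptor for prostaglandin E2, by 2.37. Flicr, a noncoding RNA next to Foxp3, rose by 3.10 (SE 0.22, 4.15e-07), the metalloprotease Adam19 by 3.16 and Cst7, a cysteine protease inhibitor, by 2.89. Among genes that fell were Klrd1, which encodes CD94 (-1.87, SE 0.23, 1.05e-04), the TEC-family kinase Txk (-1.23, SE 0.13, 3.57e-05), and Pdk1, a kinase that inhibits pyruvate dehydrogenase (-1.18, SE 0.14, 6.54e-05).

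Cish, a target of STAT5, rose by 3.33 (SE 0.19, limma adjusted p = 2.87e-08) beside Il2ra and Il2rb, and a wider IL-2 and STAT5 response is a possible explanation. Of 8 further response genes, 3 rose (Lta by 1.19, Socs1 by 1.00 and Pim1 by 0.99) while Socs3 showed -0.36, and their median was 0.29. The camera p was 7.26e-04, and 0.0628 with an estimated correlation, so the test leaves this open.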
